A study of Homo sapiens with 3 samples.

How the data were processed

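Total RNA of 3 HCT116 cell populations was amplified and labelled with Cy5 after the protocol of the manufacturer Toray, per the labels, and 1 array per population was read in 1 colour. The groups are those of the labels, Dicer-disrupted, Dicer-intermediate and Dicer wild-type, with 1 array each. The number of arrays limits the precision of the values.

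The deposited scanner files hold, per the file headers, the median spot intensity at 635 nm and the median intensity around each spot, from scans at 3 gains combined by fitted lines. They are neither background subtracted nor scaled. The scanner software is not given in the sources used here. The local background followed the spot's own signal (correlation of logs 0.971, 0.982 and 0.989 on the disrupted, intermediate and wild-type arrays), so it was not subtracted. The authors' deposited table of scaled intensities was compared with the scanner values. From the values, not from a label, each of its columns equals the spot median minus the 5% trimmed mean of the array's blank spots, times 1 factor per array (0.613, 0.494 and 0.806) that sets the median of the detected probes to 25, to within 0.00502. It is on a linear scale and is not centred per gene. Probes not above the trimmed blank mean plus 2 SD are empty there, and so are 2 gene probes with flagged spots on the intermediate array, which were left out on all arrays here.

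Intensities were corrected with normexp (offset 50, fitted on all spots) in limma 3.58.1 under R 4.3.3. Control spots were then removed, log2 intensities were quantile normalized over the 3 arrays, and values not above the detection limit were set to the lowest detected value of their array. The plan had named log2 as the last step, and here it came before the quantile step. The detection limit was the mean plus 2 SD of the 2680 blank spots of an array after trimming 5% at each end, or 39.6, 42.0 and 40.8 intensity units on the disrupted, intermediate and wild-type arrays. A gene counted in a comparison if its probe was detected on at least 1 of the 2 arrays. For the gene lists, the overlap of genes and the correlation of differences, detection on any of the 3 arrays was enough. Some differences there, such as that of DROSHA between the disrupted and wild-type arrays, therefore lie between 2 values at the floor. A difference against an array where the probe was not above background is a bound, written as at least. Differences were summarized with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 and drawn with matplotlib 3.10.9.

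Probes were named through the platform annotation given with the series. Of 24458 probes, 20235 had 1 symbol, 0 had several and 4223 were unnamed here. Of the symbols, 17237 were current in the gene table of assembly GRCh38.p14, 2899 were updated through its synonyms and 99 were kept as the annotation gives them. No genome build is named by the array files, so no coordinates are given. The brightest probe stood for each of 17558 genes, and 2560 genes had further probes. Among genes at least 2-fold different whose other probes were detected on both arrays, those probes had the same sign for 15 of 18 genes on the disrupted against the wild-type array, 93 of 103 on the intermediate against the wild-type array and 44 of 53 on the intermediate against the disrupted array (83.3%, 90.3% and 83.0%).

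With 1 array per group no test between groups was possible. Genes at least 2-fold apart were counted, and 33 gene lists fixed before the data were examined were described by their median difference and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Lists with under 3 measured genes have no percentile. The named genes follow a rule fixed at the same time. It takes the microRNA machinery, the 12 largest differences each way between the disrupted and wild-type arrays and 8 each way in the other comparisons among genes at least 2-fold apart under quantile and median scaling and detected on both arrays, 3 each way detected on only 1 of the first pair, 6 graded genes each way, 6 each way with the intermediate array outside both others, and up to 4 members per list. A family of near-identical copies counts once. One gene that the rule takes is not reported here. Further list members were named after their values were seen.

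On simulated arrays with spot noise of 0.15 log2 SD and 200 changed probes, counting at 2-fold on the disrupted against the wild-type array (16030 genes) found 40 of 40 genes raised 6-fold, 32 of 43 raised 3-fold, 28 of 42 lowered 6-fold and 17 of 39 lowered 3-fold, and 0 of 15866 unchanged genes. The changed probes were drawn only from probes brighter than the median gene probe of the wild-type array, so recovery among dimmer genes was not measured. On the real arrays the positive control spots, 24 of each kind, varied with an SD of 0.07 to 0.23 log2, which measures spots of 1 array and not cultures.

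The alternatives planned at the same time were median, 75th percentile and cyclic loess scaling, no background correction, offset 16, the authors' scaled intensities, a detection limit 2 times as high, no filter or floor, detection on all 3 arrays, a 3-fold threshold, the mean of a gene's probes and unmatched random lists. Normexp with blank spots as negative controls, and subtraction of the blank mean with no offset, were added after the data were seen.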

Results

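Gene expression was measured in HCT116 cells, an established human colon carcinoma line, at 3 levels of Dicer, the ribonuclease that cuts precursor hairpins into mature microRNAs. One array came from cells in which the Dicer gene had been disrupted, 1 from cells with an intermediate amount of Dicer protein, and 1 from cells with wild-type Dicer. The labels do not say whether the wild-type cells are the parental line, so differences from them may include differences between populations other than Dicer. The labels describe disrupted cells that received a tetracycline-inducible Dicer gene and were kept in 100 pg/ml tetracycline, and the intermediate array was read as coming from these cells. The purpose was to find expression that depends on the level of Dicer protein. Each group had 1 array, so no difference below has a replicate check, no p-value or standard deviation is given, and every statement describes these 3 arrays. The arrays are named after their labels throughout as the disrupted, intermediate and wild-type arrays. Of 24460 gene probes, 20817 (85.1%) were above the detection limit on the disrupted array, 21152 (86.5%) on the intermediate array and 20912 (85.5%) on the wild-type array. The median gene probe lay 25.5, 32.1 and 19.3 intensity units above the blank spots on the same arrays, against limits only about 1 unit above the blanks, so many detected genes were dim. Differences are given as log2 of normalized intensity. An offset added to all intensities shrinks the differences of dim genes, so the difference in the authors' scaled intensities is given as well where it is over 1.5 times larger or smaller as a fold. Such a fold is uncertain where 1 of its values is near background, since spots without a probe also passed the limit, 74 of 116 on the wild-type array.

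The DICER1 signal did not follow the labels. Its normalized log2 intensity was 6.14 on the disrupted array, 6.11 on the intermediate array and 5.91 on the wild-type array, and the authors' scaled intensities were 11.5, 10.6 and 5.09, all below the median of 25 of the detected probes. Where the DICER1 probe lies relative to the disrupted part of the gene is not given in the sources used here, so this signal checks neither the disruption nor the protein level. The list had a median of 0.03 at percentile 92.7 on the disrupted and of 0.06 at percentile 92.1 on the intermediate against the wild-type array. None of the 13 measured genes of microRNA biogenesis and silencing differed 2-fold in normalized intensity in any comparison. In the authors' intensities DICER1 was at 1.18 on the disrupted and 1.06 on the intermediate against the wild-type array, and on the latter AGO4 was at 1.13 and XPO5 at -1.50. XPO5 was also at -1.06 there against the disrupted array. AGO2, the slicing Argonaute protein, was 0.67 higher on the disrupted than on the wild-type array. XPO5, which exports precursor microRNAs from the nucleus, was at -0.30 in that comparison and at -0.97 on the intermediate against the wild-type array. PRKRA and TARBP2, which bind Dicer, differed by 0.19 and 0.03 between the disrupted and wild-type arrays. DGCR8, a partner of DROSHA in making the precursor hairpins, differed by 0.04, and DROSHA itself was not above background on either array. AGO1, AGO3, AGO4, TNRC6A, TNRC6B and TNRC6C lay between -0.05 and 0.07.

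The first comparison asked what differs between cells with disrupted and with wild-type Dicer. Genes of the interferon response were lower on the disrupted array, with IFI27 at -4.33, BST2 at -4.19 and IFI6 at -3.56. In the authors' scaled intensities these were -6.11 for IFI27 and -6.40 for BST2. BST2 encodes tetherin, which holds budding viruses at the cell surface. IFI6 stood at 133 authors' units on the disrupted array and 2141 on the wild-type array. IFIT1, ISG15, OASL and IFITM1, all interferon-induced antiviral genes, were at -2.32, -2.24, -2.02 and -1.97, or -3.55, -2.58, -3.61 and -2.81 in the authors' intensities. Among the genes lower on the disrupted array were also CSTA, a cysteine protease inhibitor, at -3.14 (-3.79 in the authors' intensities), and SLPI, a serine protease inhibitor, at -1.76. GDI2, which recycles Rab proteins, was at -1.63, and a separate probe of GDI2 gave -1.57. The olfactory receptor genes OR10G6 and OR9I1 were at -1.74 each, and at -4.17 and -2.42 in the authors' intensities.

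The genes furthest above wild-type on the disrupted array were PPARGC1A, a coactivator of mitochondrial genes, at 3.82 (8.63 in the authors' intensities), the cytokine gene IL15 at 3.61 (5.13) and the pseudogene DNM1P17 at 3.49 (7.57). On the wild-type array PPARGC1A and DNM1P17 were at only 1.11 and 1.85 authors' units, near background, so their folds in the authors' intensities are uncertain. The other 2 probes of IL15 averaged -0.06 and the other probe of NFKB2, whose first probe gave 2.13 (3.39), was at -0.17, so the signals for IL15 and NFKB2 rest on 1 probe each. KRTAP2-1, a keratin-associated protein gene, was at 2.77. HCP5, TFAP2E, TBL2 and ZBED2 were at 2.65, 2.13, 2.12 and 1.96, or 3.65, 3.62, 2.83 and 3.50 in the authors' intensities. ZBTB20, a transcriptional repressor, was at 1.80, TIPARP, a target of the aryl hydrocarbon receptor, at 1.78, and SLC2A1, the glucose transporter GLUT1, at 1.77. NPR3 was detected on the disrupted array and not above background on the wild-type array, a difference of at least 2.80, as were TM4SF18 and ICAM1 with at least 0.91 and 0.50. In the authors' intensities these bounds were 7.88, 5.14 and 4.11. In the other direction, LRRC63 and AGBL2 were detected on the wild-type array alone of the pair, with log2 differences of -0.69 and -0.41 as bounds, or -4.59 and -3.76 in the authors' intensities.

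In all, 64 of 15797 genes were at least 2-fold higher and 37 at least 2-fold lower on the disrupted than on the wild-type array, a count of 101 or 0.639%. The count depends on the processing. In the authors' scaled intensities, which differ in background, offset and scaling, 512 were higher and 252 lower. Quantile normalization after blank subtraction with no offset gave 507 and 247, so background and offset rather than scaling went with the larger counts. Quantile normalization with neither background correction nor offset gave 76 and 45, but there the blank level stays in every value and acts as an offset. Scaling to the median in place of quantile normalization gave 111 higher and 27 lower, moving the share of higher genes from 63.4% to 80.4%.

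By gene list, 8 of the 24 measured interferon and double-stranded RNA response genes were at least 2-fold lower on the disrupted array and none was higher. The authors' intensities put 14 of the 24 lower and none higher. Their median difference was -0.53, at percentile 0.0 of 10000 random lists matched on expression, and -1.39 in the authors' intensities. OAS3, IFIT2 and OAS1 were at -1.28, -1.13 and -1.05, the latter pair at -1.95 and -2.99 in the authors' intensities. Of the 17 mitotic genes none reached 2-fold, yet their median was 0.43, at percentile 100.0, with TOP2A at 0.90, NUSAP1 at 0.84, CCNA2 at 0.69 and CCNB1 at 0.66. In the authors' intensities 3 of them were at least 2-fold higher and none lower, TOP2A at 1.20, CENPE at 1.77 and CENPF at 1.77, the latter pair at 0.44 and 0.60 in normalized intensity. Separate probes of TOP2A and CCNB1 gave 0.76 and 0.26 in normalized intensity. The 19 DNA replication genes had a median of 0.15 at percentile 97.51, with CCNE2, which drives entry into S phase, at 1.46, RRM2 at 0.73 and MCM7 at -0.82. A separate probe of RRM2 was at -0.11. The 17 DNA repair genes had a median of 0.11 at percentile 98.1, with BRCA1 at 0.50. A median outside the middle 95% of random lists, the bounds used here, was found again in 13 of 13 alternative settings for the interferon and mitotic lists, in 11 for replication and in 9 for repair. Random lists gave the percentile as a description of these arrays. Of 99 such list medians over the 3 comparisons, 36 lay outside these bounds, where 4.95 would for lists of randomly drawn genes. Genes of a list can vary together, lists share members, and 1 comparison follows from the other 2. The 4.95 is therefore not the number that these lists would give without an effect of Dicer.

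Published targets of microRNAs were the lists closest to Dicer's function. The 112 measured genes of the combined target lists had a median of 0.02 on the disrupted against the wild-type array, at percentile 99.8 of random lists, with 3 genes at least 2-fold higher and none lower, or 8 higher and none lower in the authors' intensities. The first 3 were CDK6 at 1.47, CCNE2 at 1.46 and CFL2, which severs actin filaments, at 1.23. The size of this shift was small, and in the authors' scaled intensities the median was 0.00 at percentile 95.03, within the bounds. It was at -0.09 under 75th percentile scaling, which shifts the median of all genes further, by -0.17. With a higher detection limit it was at -0.03, where the median of all counted genes was -0.04. By microRNA, the medians and percentiles were 0.07 and 99.4 for miR-200 family targets, 0.16 and 98.9 for miR-15/16 targets, 0.06 and 97.9 for miR-29 targets and 0.07 and 96.5 for miR-34 targets. Of 13 alternative settings 11 kept the call of the miR-200 and of the miR-15/16 list and 4 that of miR-29. CDK6 belongs to the miR-15/16, miR-29 and miR-34 lists. Targets of let-7, the miR-17 family and miR-21 lay inside the bounds, at percentiles 59.3, 66.0 and 9.90. Of the let-7 list 13 members were above 0 and 14 below, with RRM2 at 0.73, SMARCAD1 at 0.37, E2F5 at -0.47, MYC at -0.38 and HMGA1 at -0.34. RHOB, of the miR-21 list, was at 0.999, and a separate probe of RHOB gave 0.525. Of the microRNA host transcripts only H19 and MIR22HG were measured, at -0.25 (-2.09 in the authors' intensities) and 0.20.

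The remaining lists lay inside the bounds in this comparison in the main setting. That held in 9 of 13 alternative settings for ribosomal protein genes, in 8 for cancer-germline genes and in 9 for epithelial genes. In the authors' intensities the ribosomal protein genes had a median of -0.45 at percentile 0.08 and the cancer-germline genes of -0.47 at percentile 0.48. Their medians ran from -0.12 for the epithelial genes, at percentile 4.02, to 0.12 for the endoplasmic reticulum and amino acid stress genes, at percentile 92.9. Single members differed more. PLK2 of the p53 targets was at 1.34 and TP53I3 at -0.72, with -0.16 from a separate probe of TP53I3. DUSP6, a phosphatase induced by MAP kinase signalling, was at 1.28, and EGR1 of the same list was at 0.96 (1.63 in the authors' intensities). DKK1, a secreted WNT antagonist, was at -1.36. CXCL8, the chemokine interleukin-8, was at 1.003. Markers of blood cells, fibroblasts, endothelial cells, hepatocytes and neurons had medians between -0.01 and 0.04.

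**Figure D1:**
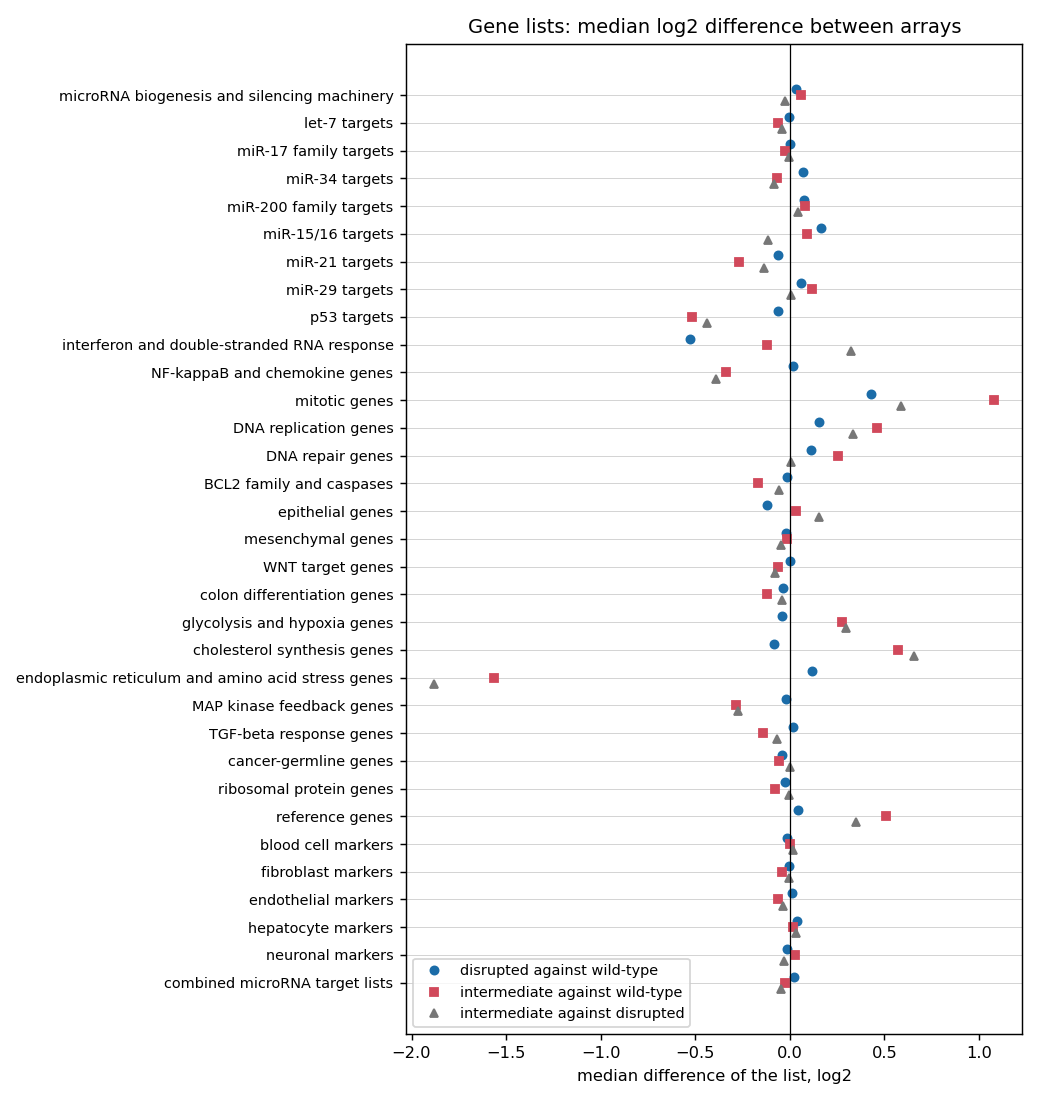
Median log2 difference (horizontal axis) of each gene list (vertical axis) in the 3 comparisons, where circles stand for disrupted against wild-type, squares for intermediate against wild-type and triangles for intermediate against disrupted. The stress genes lie at -1.56 on the intermediate against the wild-type array, the mitotic genes at 1.08, and the interferon genes at -0.53 on the disrupted against the wild-type array.

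The intermediate array was set against the wild-type array to ask how cells with a partial amount of Dicer differ. Genes of the response to amino acid shortage and endoplasmic reticulum stress were far lower on the intermediate array. DDIT4, an inhibitor of mTORC1, was at -4.32, CHAC1, which degrades glutathione, at -3.99 (-4.99 in the authors' intensities), and ASNS, asparagine synthetase, at -3.18. Of the 18 measured genes of this list 13 were at least 2-fold lower and none was higher, with a median of -1.56 at percentile 0.0. SESN2, DDIT3, TRIB3 and ATF3 were at -2.61, -2.56, -2.52 and -2.47 (ATF3 -3.19 in the authors' intensities), and DDIT3, TRIB3 and SESN2 had been at 0.61, 0.42 and -0.07 on the disrupted against the wild-type array. ATF4, the transcription factor upstream of several of these genes, was at -1.05, but its other probe was at 0.34.

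The largest difference was that of LCN2, an iron-sequestering secreted protein, at -5.82 (-8.16 in the authors' intensities). UPP1, uridine phosphorylase, was at -4.61. HBE1, embryonic globin, was at -4.20 (-5.21), and its other probe gave -4.25. IFI27 and SLPI were at -3.92 and -3.33, or -5.02 and -5.11 in the authors' intensities. The genes furthest above wild-type were KRTAP2-1 at 3.46, the keratin gene KRT23 at 2.72 (5.87), CAVIN3, a caveolar coat protein, at 2.66 (3.39), and KITLG, the ligand of the KIT receptor, at 2.64, with 1.79 from a separate probe. SPTSSB, CLU, VSNL1 and SLC2A1 were at 2.48, 2.37, 2.31 and 2.21, and SPTSSB and VSNL1 at 5.98 and 3.46 in the authors' intensities.

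Mitotic genes were higher on the intermediate array, 9 of 17 by at least 2-fold, with a median of 1.08 at percentile 100.0. TOP2A, CCNB1, BUB1 and KIF20A were at 1.99, 1.85, 1.78 and 1.69, with BUB1 at 2.65 in the authors' intensities. DNA replication genes had a median of 0.46 at percentile 99.9, with 4 of 19 at least 2-fold higher and RRM2 at 1.88, though its other, dimmer probe was at -0.11. Of 15 cholesterol synthesis genes 5 were at least 2-fold higher, with a median of 0.57 at percentile 99.9. IDI1, STARD4, FDFT1 and SC5D were at 1.31, 1.11, 1.09 and 1.09, and SQLE at -0.81. STARD4 was at 2.07 in the authors' intensities. The p53 targets had a median of -0.52 at percentile 0.010, with 6 of 26 at least 2-fold lower (10 in the authors' intensities). Among them were SESN2, which is also a stress list member, GDF15 at -2.43 (-3.03 in the authors' intensities), GADD45A at -1.90 and BBC3 at -1.89. In this list 19 members were below 0 and 7 above, with BAX at 0.57. Whether its difference is separate from that of the stress genes was not tested. NF-kappaB and chemokine genes had a median of -0.34 (-1.45 in the authors' intensities) at percentile 0.0, with NFKBIA at -1.24 and CXCL2 at -1.20 (-2.95), while NFKB2 was at 2.08 (3.32) by its first probe and at -0.37 by its other. Interferon genes had a median of -0.12 at percentile 0.22, with 4 of 24 at least 2-fold lower, or 8 in the authors' intensities.

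Targets of miR-21 had a median of -0.27 on the intermediate against the wild-type array, at percentile 0.0, with none of 15 differing 2-fold. MARCKS, RHOB, BTG2 and SPRY1 were at -0.69, -0.65, -0.63 and -0.54. In the authors' intensities 2 of the 15 were at least 2-fold lower, SPRY1 at -2.49 and BTG2 at -1.05, and 1 was higher, RECK at 1.82 (0.09 in normalized intensity). RECK was near background, at 0.9 authors' units on the wild-type array. Targets of miR-29 had a median of 0.12 at percentile 98.3, a call held in only 3 of 13 alternative settings. The combined microRNA target lists had a median of -0.02 at percentile 21.3. MYC, which the let-7 and WNT lists share, was at -2.81 and HMGA1 at -1.98. The percentiles of the other microRNA target lists lay between 5.95 for let-7 and 95.1 for the miR-200 family. In the authors' intensities the miR-200 targets had a median of 0.53 at percentile 99.85, with 6 of 18 at least 2-fold higher and none lower. DNA repair genes (median 0.25, percentile 98.8), glycolysis and hypoxia genes (0.28, 99), TGF-beta response genes (-0.14, 0.340) and colon differentiation genes (-0.12, 0.120) were outside the bounds too. The repair call held in 7 of 13 alternative settings and the colon differentiation call in 9. LDHA was at 1.63 and HK2 at -1.48, or 1.01 and -2.41 in the authors' intensities. The 12 reference genes, used for scaling in other assays, had a median of 0.51 at percentile 99.5, but -0.23 at percentile 42.5 in the authors' intensities, which differ in background, offset and scaling, and the call held in 8 of 13 alternative settings. Ribosomal protein genes had a median of -0.08 at percentile 19.1, and -0.71 at percentile 0.5 in the authors' intensities. BCL2 family, epithelial, mesenchymal, WNT target, MAP kinase feedback and cancer-germline genes lay inside the bounds, which 6 of 13 alternative settings kept for the MAP kinase feedback genes and 9 for the BCL2 family. Inside them were also the markers of other cell types, whose medians ran from -0.06 to 0.03.

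On the intermediate array 318 of 15948 genes were at least 2-fold higher and 266 at least 2-fold lower than on the wild-type array, 584 or 3.66%, against 101 for the disrupted array. Scaling to the median gave 681 higher and 138 lower and moved the share of higher genes from 54.5% to 83.2%. The authors' scaled intensities gave 1369 higher and 919 lower.

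Against the disrupted array, the intermediate array showed which genes differed between the cells labelled intermediate and disrupted. Interferon genes were higher on the intermediate array, with IFI6 at 2.71 and IFIT1 at 1.22 (2.17 in the authors' intensities), and a list median of 0.32 at percentile 100.0. ALDOC, a glycolytic aldolase, was at 2.36 with 2.16 from a separate probe, GCHFR at 2.16 (3.90 in the authors' intensities), CPOX, an enzyme of haem synthesis, at 1.98, CAVIN3 at 1.97, TMSL8 at 1.94 (2.68), KITLG at 1.86 and SPTSSB at 1.80 (2.83). Stress genes were lower, 13 of 18 by at least 2-fold, with a median of -1.88 at percentile 0.0 and DDIT4, CHAC1, ASNS and DDIT3 at -4.25, -3.63, -3.27 and -3.18 (CHAC1 -4.47 in the authors' intensities). LCN2 was at -4.62 (-6.73) and UPP1 at -4.45. PPARGC1A and IL15 were at -3.80 (-8.05) and -3.32 (-4.33), and the other probes of IL15 averaged 0.08. PPARGC1A stood near background on the intermediate array, at 1.65 authors' units.

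Mitotic genes had a median of 0.59 and cholesterol synthesis genes of 0.66 on the intermediate against the disrupted array, both at percentile 100.0. Replication genes were at 0.33 (percentile 99.5), glycolysis and hypoxia genes at 0.30 (99.9) and reference genes at 0.35 (98.4), and of 13 alternative settings 8 kept the glycolysis and the reference call. The p53 targets were at -0.44 and the NF-kappaB and chemokine genes at -0.39 (-0.92 in the authors' intensities), both at percentile 0.0. Targets of miR-21 (-0.14, percentile 0.225), mesenchymal (-0.05, 1.62), MAP kinase feedback (-0.27, 1.52) and TGF-beta response genes (-0.07, 1.89, but -0.74 in the authors' intensities) were lower, and the call held in 12, 10, 9 and 10 of the settings. The combined microRNA target lists had a median of -0.05 at percentile 0.110, with 2 genes at least 2-fold higher and 6 lower, or 5 and 12 in the authors' intensities. In total 146 of 15902 genes were at least 2-fold higher and 197 lower. Median scaling gave 275 higher and 150 lower, a share of higher genes of 64.7% against 42.6%, and the authors' scaled intensities gave 813 and 607, a share of 57.3%.

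**Figure D2:**
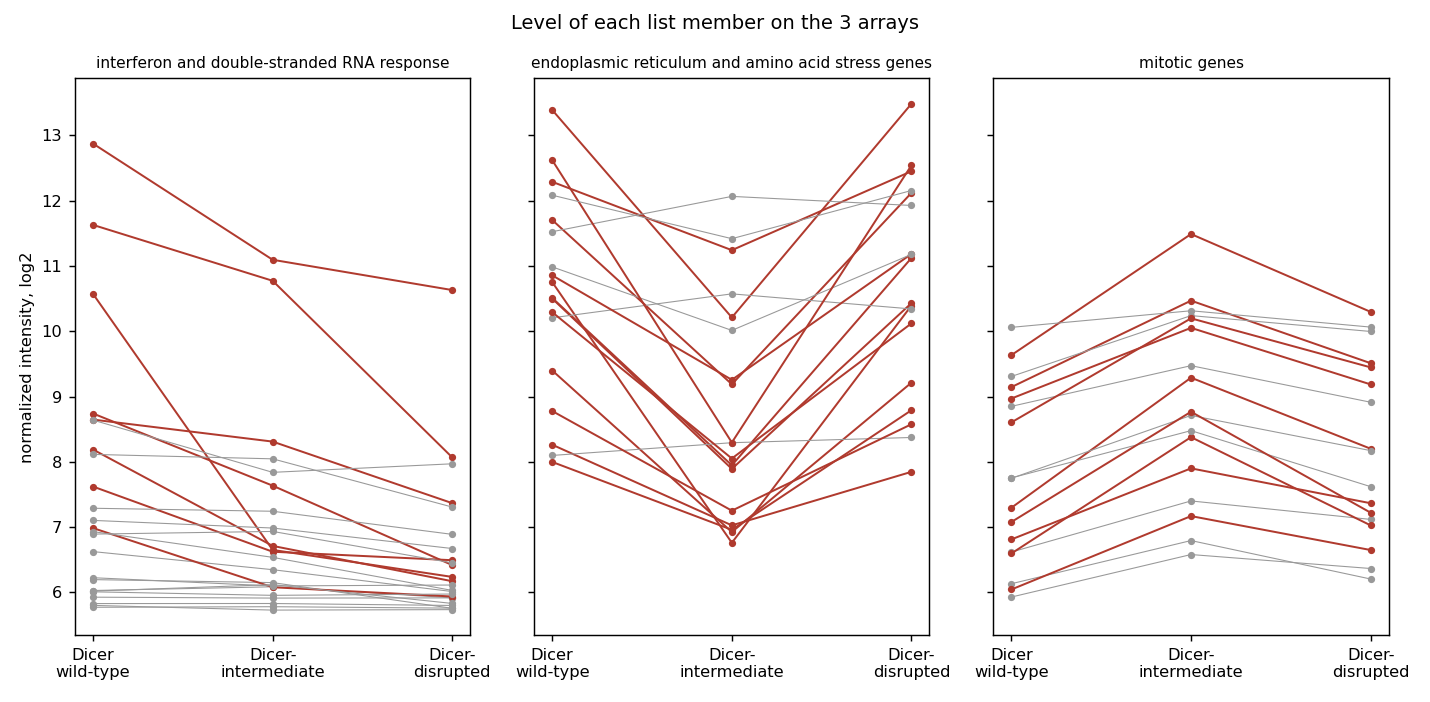
Normalized log2 intensity (vertical axis) of every measured member of 3 gene lists on the 3 arrays (horizontal axis), 1 line per gene. Red lines are genes at least 2-fold apart between the disrupted and wild-type arrays (interferon list, 8 of 24) or between the intermediate and wild-type arrays (stress list, 13 of 18, and mitotic list, 9 of 17).

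Few genes were ordered by the amount of Dicer with a span of at least 2-fold. Of 707 genes that were detected on all 3 arrays and spanned at least 2-fold, the intermediate array held the middle value for 42 (5.94%), the disrupted array for 490 and the wild-type array for 175. It can hold the middle only where the disrupted and wild-type arrays are at least 2-fold apart, which held for 99 genes. The share of 5.94% is bounded by that count, so it does not weigh against an order by Dicer among those genes. Only 3 genes were higher by at least 0.5 at each step from wild-type through intermediate to disrupted, ZBED2, PLK2 and ABCE1, and 5 were lower at each step, CSTA, BST2, IFIT1, IFI6 and OASL. ABCE1, a ribosome recycling factor, was at 8.54, 9.09 and 9.94 in that order, and CSTA at 10.43, 8.81 and 7.29. In the authors' intensities further genes passed 0.5 at each step, among them IFI27, IFIT3, IRF9 and OAS1 as lower genes and HCP5 as a higher one. The intermediate array lay at least 2-fold above both others for 98 genes and below both for 139. TSC22D3, a glucocorticoid-induced gene, was the sixth of these by distance to the nearer array, at 7.36 against 10.12 on the disrupted and 10.04 on the wild-type array.

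Over the 100 genes at least 2-fold apart between the disrupted and wild-type arrays and detected on both, the median position of the intermediate array was 1.01, on a scale where 0 is wild-type and 1 is disrupted. The intermediate value lay between the others for 42 genes, beyond disrupted for 51 and on the far side of wild-type for 7. Unchanged arrays with equal noise were simulated 100 times, with the noise of 0.0799 log2 SD per array set from the median spread of the differences between the disrupted and wild-type arrays. It does not measure variation between cultures. The 100 genes furthest apart in each simulation, picked by rank and not by the 2-fold threshold, had a median position of 0.499. Across 16069 genes, which are not independent replicates, the difference of the disrupted from the wild-type array correlated with that of the intermediate array, with Pearson's r 0.549 and Spearman's rho 0.519. Unchanged arrays sharing the wild-type array gave r 0.501 in simulation. The covariance was 0.0582 against 0.0064 simulated, which is the square of the noise put in, so the gap does not separate a shared effect from variation between cultures. Of the 64 genes higher on the disrupted array 41 were also at least 2-fold higher on the intermediate array and 2 at least 2-fold lower, and of the 37 lower genes 26 were lower and 0 higher there. The 2 opposite genes, named after their values were seen, were CXCL8 at 1.003 and -1.08 and DHRS2 at 1.503 and -1.05 (-1.72 in the authors' intensities) on the disrupted and intermediate against the wild-type array. In the simulations, which hold the shared wild-type array and no effects, as many genes taken from the top of each ranking shared 15.7 on average and at most 24 for the higher genes, and 9.86 and at most 17 for the lower genes. The simulations gave every gene the same noise. Genes with noisier wild-type spots would be shared more often, so they may understate the overlap without an effect. Independent lists, which hold no shared array, would share 1.27 and 0.612. Part of the excess over either may come from the shared wild-type array, which cannot be split.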

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

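Tests of the graded Dicer explanations of the counts and of the stress genes, of scaling and Dicer level for the interferon genes, of scaling for the stress genes, and of the number of list genes that were lower, were chosen after related values had been seen. The patterns and the tests come from the same 3 arrays.

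Probes unnamed here, which enter no comparison, also differed. On the disrupted array 7 were at least 2-fold above wild-type and 3 below, and on the intermediate array 24 above and 50 below. All 24 spots of the first negative control exceeded the detection limit on the intermediate array, against 14 on the disrupted and 8 on the wild-type array, with means of 43.5, 39.8 and 40.6 intensity units. Other controls went otherwise, with 48 of 116 spots without a probe above the limit on the intermediate array, 34 on the disrupted and 74 on the wild-type array, and 0 spots of the second and of the third negative control on the intermediate array.

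The intermediate array differed from wild-type at more genes than the disrupted array did. Other probes of the genes that differed 2-fold had the same sign for 90.3% of genes (95% exact interval 82.9% to 95.2%), which argues against faults of single spots. After cyclic loess the ratio of the 2 counts was still 6.07, and the 3 fullest of 24 slide blocks held 19.5% of the genes, against scaling that depends on intensity and against a fault of part of the slide. A response graded by Dicer level alone would make the disrupted array the more distant one, and the ratio of 5.78 goes against it. The ratio cannot exclude a graded response beside another difference, which would add genes to the count of the intermediate array. A difference between the cell populations other than Dicer, or between cultures or hybridisations, stays open because each group is 1 array.

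Interferon genes were lower on the disrupted array. Scaling is argued against by a list median of at most -0.47 under 4 other scalings, and scattered faults of single spots by 8 list genes at least 2-fold lower, where the highest of the matched random lists held 2. Only 1 of these genes, IFIT2, had another probe, at -0.94, which is too few to decide about single spots by that route. The list median on the intermediate array, -0.12, lay between those of the others, and 14 of 24 members were in that order, so an interferon tone that follows Dicer level is a candidate explanation. The order lends it little support, because under equal noise alone genes with a gap between 2 arrays tend to have the other array between them. On simulated unchanged arrays this held for 91.5% of the genes furthest apart, picked by rank. None of those reached 2-fold, and the interferon list was fixed beforehand, so 91.5% is not the share to set against 14 of 24. On the real arrays the intermediate lay between for 42 of the 100 genes at least 2-fold apart. With 1 array per group an interferon tone cannot be separated from other differences between the populations.

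Stress genes were lower on the intermediate array. Their median was at most -1.28 under 4 other scalings, and 13 genes were at least 2-fold lower where random lists held at most 6, which argues against scaling and scattered spot faults. The 1 other probe available, for ATF4, went the opposite way at 0.34, which is too few to decide and leaves the difference of ATF4 on 1 probe. Dicer level as a graded cause is argued against by the disrupted array, at 0.12 from wild-type. Medium, density or tetracycline could each differ between the cultures and were not tested.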

How the results depend on the processing

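Blank subtraction without an offset, and normexp with blank spots as controls, were added after the data were seen. Leaving out an array was not possible with 1 per group. Of the values that answer a comparison, 82 stayed within their spread, 43 moved and 2 reversed. With 1 array per group that spread holds no variation between cultures, so staying within it is not agreement within experimental error. Of the other values, 3843 stayed, 848 moved and 9 reversed. Reversals under 75th percentile scaling come with its shift of all genes, and relative to that shift the lists stayed higher, except the miR-29 targets on the intermediate against the wild-type array. Of 69 named differences of at least 2-fold, 68 kept their size class and direction in every setting, and NFKB2 was at 0.98 with the mean of its probes. Where no construction is named, the cause was not tested.

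Counts are given as higher then lower. Disrupted against wild-type gave 145 and 71 with offset 16, 512 and 252 in the authors' intensities, 507 and 247 with blank subtraction, 14 and 13 at 3-fold, and 111 higher with median scaling. Intermediate against wild-type gave 566 and 421, 1369 and 919, 1346 and 889, 63 and 69, and 681 and 138 in the same order. Intermediate against disrupted gave 283 higher with offset 16, 813 and 607, 790 and 638, 17 and 56, and 275 higher with median scaling. A smaller offset shrinks dim differences less and a higher threshold passes fewer genes, by construction.

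The position of the intermediate array was 1.14 with median scaling and 1.08 with a detection limit 2 times as high. The correlation of the 2 differences from wild-type was 0.603 with median and with 75th percentile scaling, 0.529 with loess, 0.567 with offset 16, 0.590 in the authors' intensities, 0.527 with the higher limit and 0.580 with blank subtraction. The combined microRNA target median was 0.049 with median scaling, 0.038 with loess, 0.040 with offset 16, 0.002 in the authors' intensities (for the combined microRNA target lists, percentile among random lists, Dicer-disrupted against Dicer wild-type, 95.8 of 2000 lists) and 0.076 with blank subtraction. It reversed to -0.091 with 75th percentile scaling and to -0.032 with the higher limit (percentile 94.6). With the higher limit the median of all counted genes was itself -0.041.

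With 75th percentile scaling, which moves the median of all genes by -0.165, -0.313 and -0.166 in the 3 comparisons, the disrupted against wild-type medians of the miR-200 and miR-29 targets reversed to -0.121 and -0.146. For the miR-29 targets, median difference, Dicer-intermediate against Dicer wild-type, the value reversed to -0.319, and that of the reference genes to -0.061. Targets of miR-29 reversed to -0.006 and -0.035 with median scaling and to -0.009 and -0.076 with the higher limit, and the reference genes to -0.230 in the authors' intensities. On the disrupted and intermediate against the wild-type array, the medians of all counted genes were -0.026 and -0.029 with median scaling. With the higher limit they were -0.041 and -0.052. The median gene probe lay 19.3 to 32.1 units above the blanks, which limits what can be said of dim genes.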

Other observations

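The gene filter and window size of the neighbour test below were chosen after an earlier look with another filter, while its prediction was written before any such look, and the genes in the next paragraph were chosen after their values were seen.

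Some further genes were lower on the intermediate than on the wild-type array and not 2-fold different on the disrupted array. DUSP5, a phosphatase acting on ERK, was at -2.53 against -0.36, and AXL, a receptor tyrosine kinase, at -1.28 against 0.01. SNAI2, a repressor of epithelial genes, was at -1.17 (-3.22 in the authors' intensities) against 0.38. The growth factor gene VEGFA was at -1.20 against -0.02. CCN1 and CCN2, matricellular proteins, were at -1.33 and -1.07 (CCN2 -2.04) against 0.56 and 0.48. ID2, an inhibitor of helix-loop-helix factors, went the other way at 1.57 against 0.22. Among globin genes, HBE1 was at -1.63 on the disrupted and -4.20 on the intermediate array, and HBD was at -1.08 and -1.76 (-1.73 and -3.74 in the authors' intensities), while HBG1 did not reach 2-fold, at -0.56 and -0.81 (-1.47 on the intermediate array in the authors' intensities). The other, dim probe of HBD was at 0.02 and 0.01. HBM, HBZ and HBQ1, further globin genes, were at 0.05, 0.11 and -0.03 on the disrupted array and at 0.02, -0.01 and -0.00 on the intermediate array.

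A hypothesis was that neighbouring genes differ together, as copy number or regional differences between the populations would give. Over 7475 genes above the median level, ordered by the gene table, the correlation of adjacent genes was 0.168 on the disrupted against the wild-type array, 0.0774 on the intermediate against the wild-type array and 0.041 on the intermediate against the disrupted array. The highest of 1000 shuffles gave 0.0382, 0.0409 and 0.037. Among windows of 25 genes, that from LARP4B to CCDC3 had the lowest median on the disrupted against the wild-type array, -0.42, where the lowest shuffled window was -0.37 and 23 genes were below 0. The window from PROSER2 to THNSL1 was lowest on the intermediate against the wild-type array, at -0.76 against -0.58, and the window from ZRANB2 to KYAT3 was highest on the disrupted array, at 0.43 against 0.39. The PROSER2 window overlaps the LARP4B window. Its median on the disrupted against the wild-type array was -0.36, with 23 genes below 0, and both comparisons share the wild-type array. No window of the intermediate against the disrupted array exceeded the shuffles, nor did the highest window of the intermediate against the wild-type array, ITGB3BP to DNAJB4, at 0.64 against 0.69. Genes 10 apart exceeded the shuffles on the disrupted against the wild-type array (0.0941 against 0.0437), but not in the others (0.0232 against 0.0344 and 0.0115 against 0.0446). Copy number differences are a candidate explanation, and regional base composition, which could bias hybridisation, was not tested.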
